A study of Mus musculus with 6 samples.

How the data were processed

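The series measured messenger RNA in C2C12 cells, a mouse myoblast line that fuses into multinucleated myotubes when serum is reduced. Per the labels' protocols, cells grown in 10% serum were moved to 2% horse serum for 4 days, until over 80% of nuclei lay in myotubes, and then infected with an adenovirus. Adenoviruses carry a transgene into non-dividing cells without entering the genome. The virus expressed green fluorescent protein alone (the GFP group) or that protein together with full-length human GLI1, the zinc finger transcription factor at the end of the Hedgehog pathway (the GLI1 group). The medium was changed 12 h after infection and cells were lysed at 60 h. Each group held 3 samples, and each sample was labelled with biotin and hybridised to its own Affymetrix whole-transcript array. The labels call the samples of a group biological replicates and do not say whether they came from separate cultures, so p-values measure the spread between these samples, part of which can be technical. No sample was left out and no 2 arrays held the same values.

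The deposited table holds 28853 probe sets, each a group of probes for a transcript region, on 6 arrays, with 0 missing values. The values are on a log scale, treated as log2, and the authors' processing left each probe set centred on its own median over the 6 arrays (the largest absolute median was 5.0e-07). The software, background correction and normalization between arrays are not given in the sources used here. The submitters' processing notes name the genome build mm9, and no position is given here because the table holds none. Log base 10 was ruled out from the values' rounding, which left uncentred values of at least 4 wherever it could be read (23420 probe sets at 4 or more and 2437 at 8 or more on every array; 2996 unresolved). Of 198 probe sets for ribosomal proteins 166 lay in the upper range, against 34 of 1023 for olfactory receptors. A natural log could not be ruled out; the folds given here would then be too small, while signs, tests and ranks would stay. Centring removed the signal level of each probe set, so no probe set could be filtered on its signal, none can be set against another, and the number of arrays limits the precision.

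Probe sets were named from the platform's annotation table, which can be old, and symbols were checked through the gene ID against a mouse gene table of assembly GRCm38.p6. There were 21789 probe sets with exactly 1 gene symbol, 1621 with several and 5443 with none. The gene ID of 91 single-symbol probe sets was not matched, and those kept their annotated symbol; 0 symbols needed an update. No gene was named from a probe set with several symbols. The 21789 probe sets stand for 19938 genes, of which 999 had more than 1 probe set. For those, the probe set with the highest mean was used; after centring this choice takes no account of signal, and the average and the most variable probe set were run as alternatives.

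All differences are GLI1 minus GFP. A linear model with 2 groups was fitted to all probe sets with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with two-sided tests and Benjamini-Hochberg adjustment over 28853 probe sets, and a call needed an adjusted p below 0.05. The moderated fit pooled the variances fully: the prior degrees of freedom were infinite, so 1 within-group SD of 0.25 applied to every probe set and each log2 difference has a standard error of 0.20. A probe set with an unusual spread is therefore judged by the common one, and a fit without moderation was added after the data had been seen. For a single gene, 3 arrays against 3 allow an exact permutation p of 0.10 at the smallest, so no single-gene permutation test can pass 0.05.

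Before the data were examined, 27 gene lists were fixed, for the Hedgehog pathway, muscle, signalling, metabolism, stress and other cell types. Each list was tested on the 19938 genes with limma's camera, which compares its genes with all others, at a preset correlation between genes of 0.01 and with adjustment over the 27 lists. Camera with an estimated correlation and fry, whose directional p asks whether the genes of a list move on balance in 1 direction, were alternatives. The rule for naming genes was fixed then too. It takes Gli1, Ptch1, Hhip and a further gene that is not reported here, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap (predicted genes and unnamed clones left out), and from every list the 2 higher and the 2 lower members with the smallest p, whether or not they pass. List members without a single-symbol probe set are not analysed here. Other genes are named only where the text says that they were chosen after their values were seen.

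The alternatives were quantile normalization, subtraction of each array's median, a trended and robust variance prior, array weights, the replicate number as a block, averaging of a gene's probe sets, stricter thresholds, and leaving out each array in turn. The planned filters on dim probe sets could not be run on centred values. The fit was tested on simulated data for the GLI1 against GFP comparison with 28853 probe sets. With the pooled SD, it recovered 7 of 50 probe sets changed by 0.5 on the log2 scale, 32 of 50 changed by 0.75, 46 of 50 changed by 1 and 50 of 50 changed by 2, with 12 false calls among 147. With each probe set's own SD as the noise, it recovered 0 of 50, 8 of 50, 25 of 50 and 48 of 50 at these sizes, with 0 false calls among 81. Those SDs were themselves estimates from 3 arrays per group, so the simulated variances differed more between probe sets than the measured ones. This second run therefore does not show how the fully pooled fit treats a probe set of unusual spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.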

Results

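Gene expression was compared between C2C12 myotubes infected with an adenovirus expressing GFP alone and myotubes infected with an adenovirus expressing GFP and human GLI1, with 3 arrays in each group. According to the design text, the series addresses the molecular basis of Sonic hedgehog signalling in skeletal muscle cells. GLI1 is a transcription factor of that pathway, one of a family with GLI2 and GLI3, and is itself a target gene. Array medians lay between -0.03 and 0.02 on the centred log2 scale. Every log2 difference below is GLI1 minus GFP and has a standard error of 0.20 from the pooled spread (n = 3 arrays per group); folds assume that the deposited log values have base 2.

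The Gli1 probe set (10373179) was 15.7-fold higher in the GLI1 group, with a log2 difference of 3.97 (adjusted p = 1.1e-82 in limma). Its centred values were -2.04 ± 0.25 in the GFP group and 1.93 ± 0.05 in the GLI1 group (SD, n = 3). The transgene is human and the probes are of mouse sequence, so the reading does not separate the vector's transcript from that of the cells' own gene. Ptch1 (10410039), which encodes the Hedgehog receptor and is a direct target of the pathway, was 5.91-fold higher, at -1.38 ± 0.21 against 1.18 ± 0.03 (log2 difference 2.56, 95% interval 2.17 to 2.96, adjusted p = 6.0e-34). Hhip, which encodes a Hedgehog-binding membrane protein and is also a pathway target, did not pass the test (log2 difference -0.19, 95% interval -0.59 to 0.20, adjusted p = 0.792). An exact two-sided permutation test of Gli1 and of Ptch1 gave p = 0.1, the smallest that 3 arrays against 3 allow.

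**Figure D1:**
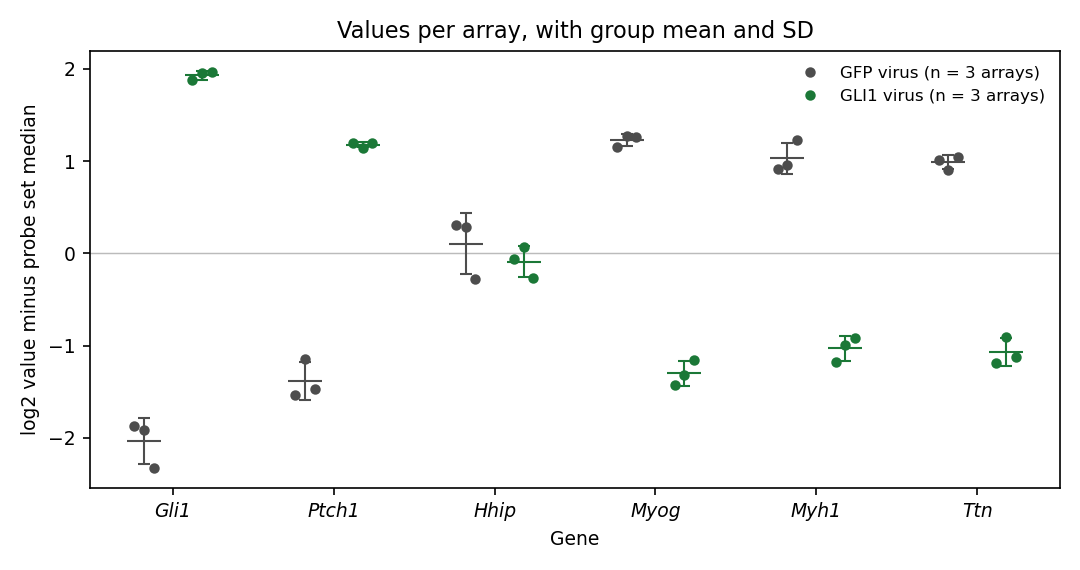
Centred log2 values (vertical axis) of 6 genes on each array, in the GFP group (grey) and the GLI1 group (green), with the group mean and SD as bars (n = 3 arrays). Gli1 and Ptch1 lay higher on all GLI1 arrays and Myog, Myh1 and Ttn lower, while the groups overlapped for Hhip.

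Expression of GLI1 was accompanied by 349 probe sets higher and 366 lower, 2.48% of the 28853 tested. Those with a single symbol stand for 290 genes higher and 327 lower, and 95 probe sets were at least 2-fold higher and 96 at least 2-fold lower. After Gli1, the largest rises were those of Gal (3.56), which encodes the neuropeptide galanin, Sox18 (3.46), a transcription factor of vascular and lymphatic endothelium, and Arc (3.33), an activity-induced gene of neurons. They were followed by Acy3 (3.15), an aminoacylase, Rcan1 (2.73), a regulator of calcineurin, the cytokine gene Il11 (2.64), the somatostatin receptor gene Sstr2 (2.64), Ptch1 and the aldehyde dehydrogenase gene Aldh3b2 (2.34). The largest fall was that of Myog, which encodes the differentiation factor myogenin, at -2.53 or 5.76-fold. Lrrn1 fell by 2.50, and the Z-disc gene Pdlim3 fell by 2.24. Myh1, a fast myosin heavy chain gene, and Ttn, which encodes titin, each fell by 2.06. Csrp3, which encodes muscle LIM protein, fell by 1.96. The muscle kinase gene Nmrk2 fell by 1.82, Cavin4 of muscle caveolae by 1.77, Klhl30 by 1.75 and Ankrd23, whose protein binds titin, by 1.70. Marchf11, chosen after its values were seen, had probe sets at -0.47 and -1.75, of which the rule took the smaller change. The adjusted p of these 20 genes was at most 2.2e-14 in limma, and all 20 kept their calls in each alternative run, including the fit without moderated variances.

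The groups did not overlap for 706 of the 715 called probe sets, and for 16.6% of all probe sets, where chance gives 10%. The counts depended on the variance model and on single arrays. Without moderation 100 probe sets were higher and 148 lower, and 193 of these were among the 715. With 1 array left out, 213 to 291 were higher and 195 to 322 lower; the higher count moved by over 1.5 times without GFP replicate 1 (226), GFP replicate 3 (224) or GLI1 replicate 2 (213), and the lower count without GFP replicate 3 (212), GLI1 replicate 1 (218) or GLI1 replicate 2 (195). Of the 68 named genes past the threshold, 42 kept their call in each of these 6 fits, and the 26 whose call ended in some, with differences of 0.65 to 0.87 in size, are pointed out where they are named. Without moderation 36 of the 68 calls ended, 25 of them among these 26 and 11 of genes that kept their call with an array left out, which are pointed out too. The same was done for the genes chosen after their values were seen, except Marchf11, for which no alternative was run.

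**Figure D2:**
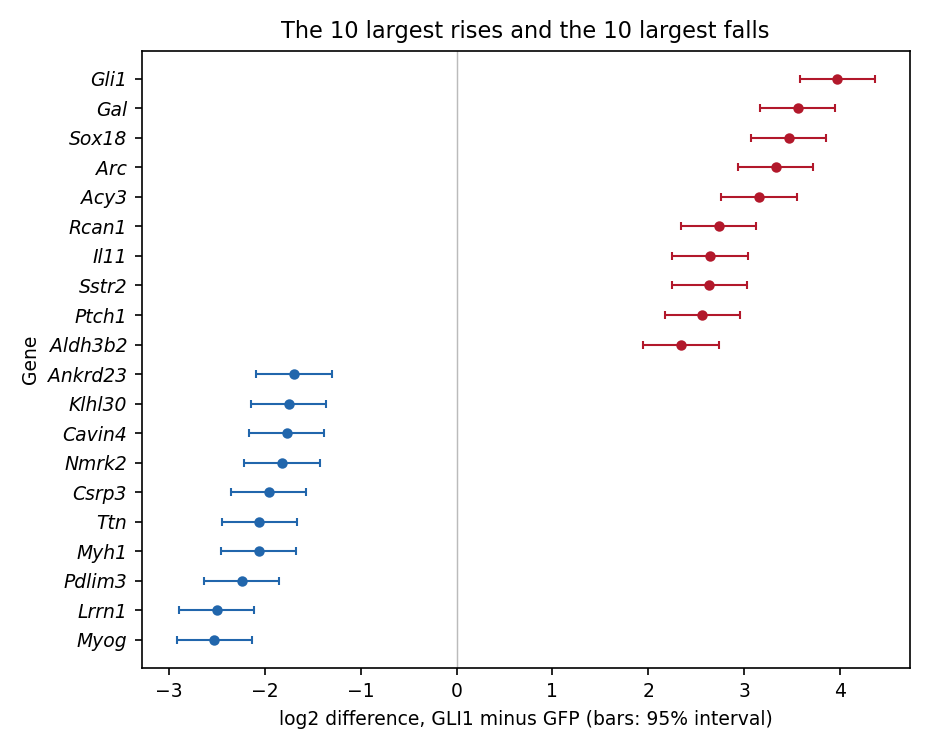
The log2 difference between the GLI1 and GFP groups (horizontal axis) with its 95% interval for the 10 largest rises (red) and the 10 largest falls (blue) among the called genes. Rises ran from 2.34 to 3.97 and falls from -1.70 to -2.53, and no interval reached 0.

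The list of known targets of the Hedgehog pathway was called higher, with a minority of its members past the threshold. Of 28 measured targets 7 rose, 0 fell and 21 did not pass (8 and 0 adjusted over the list alone). Besides Gli1 and Ptch1 the risers were Foxs1 (1.71), Foxc2 (1.30), Ccnd1 (1.25), Foxd1 (0.87) and Bcl2 (0.77), 4 of them genes of transcription factors or cyclin D1 and the last of an inhibitor of apoptosis; these 5 were chosen after their values were seen. The call of Bcl2 ended in 3 of the 6 fits with an array left out (adjusted p of up to 0.0801, without GFP replicate 1), and those of Foxc2, Foxd1 and Bcl2 ended without moderation (adjusted p = 0.104, 0.081 and 0.0729). The list's median was 0.12 and its mean 0.45 (camera adjusted p = 3.4e-13; adjusted p = 0.0159 with an estimated correlation), and without Gli1 its median was 0.09 (adjusted p = 4.1e-07). The list without Gli1, the gene of the vector, was tested with the preset correlation only. The median of the full list was 0.07 without GLI1 replicate 2 and 0.06 with array weights, with the call kept. The lower members with the smallest p did not pass: Foxf1 had -0.29 on the probe set used and 0.42 on another, and Hsd11b1 had -0.29. The 23 measured components of the pathway, its receptors, co-receptors and transducers, did not shift together (median -0.14, -0.18 to -0.04 with 1 array left out, camera adjusted p = 0.313). Among them 1 fell, 0 rose and 22 did not pass (1 lower and 1 higher adjusted over the list alone). The member that fell was Gas1, a co-receptor gene, at -0.66 (adjusted p = 0.0413), and its call ended in 5 of the 6 fits with an array left out (adjusted p of up to 0.384, without GLI1 replicate 2). The co-receptor gene Boc had 0.61, the repressor gene Sufu 0.34 and Gli3 -0.40, none past the threshold.

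Genes of muscle differentiation and contraction were lower. Of 19 myogenic regulators 7 fell, 0 rose and 12 did not pass (8 lower and 1 higher adjusted over the list alone). Next to Myog these were the fusion genes Mymx (-1.60, 3.04-fold) and Mymk (-1.03), the determination genes Myod1 (-1.37) and Myf5 (-0.72), Mef2c (-1.17) and Klhl41 (-1.23), of which all but Mymx were chosen after their values were seen. The call of Myf5 ended in 4 fits with an array left out (adjusted p of up to 0.192, without GLI1 replicate 2) and without moderation (adjusted p = 0.0951). Tead4 (0.50) and Mef2d (0.21) were the highest members and did not pass. The list's median was -0.21 and its mean -0.55 (camera adjusted p = 3.0e-12; adjusted p = 0.0201 with an estimated correlation). That median was -0.14 without GFP replicate 1, -0.37 without GFP replicate 2 and -0.12 without GLI1 replicate 3, with the call kept. Of 44 sarcomere genes 25 fell, 1 rose and 18 did not pass (32 lower and 1 higher adjusted over the list alone), and the median was -0.68 (camera adjusted p = 5.0e-35; adjusted p = 0.0236 with an estimated correlation). Beside Myh1 and Ttn, the myosin heavy chain genes Myh3 (-1.41), Myh4 (-1.35), Myh8 (-1.21), Myh7 (-1.13) and Myh2 (-0.91) fell, as 5 genes chosen after their values were seen. The calls of Myh4 and Myh2 ended without moderation (adjusted p = 0.103 and 0.0871). Probes of these near-identical paralogs can share signal. The riser was Myl2, the regulatory light chain of slow and cardiac myosin, at 1.68 or 3.20-fold (adjusted p = 4.8e-14), and Mylk4, the next highest, had 0.21 and did not pass. Of 27 genes of excitation-contraction coupling and the neuromuscular junction, 15 fell, 0 rose and 12 did not pass (20 and 0 adjusted over the list alone), with a median of -0.68 (camera adjusted p = 9.1e-21; adjusted p = 0.0159 with an estimated correlation). Musk, the receptor kinase of the junction, fell by 1.69 and Cacng1, a calcium channel subunit, fell by 1.35; Dok7 (0.19) and Sln (0.08) were highest and did not pass. On the same arrays the extracellular matrix list had a median of -0.27 and the fibroblast and undifferentiated myoblast list one of -0.16.

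Angiogenic factors moved in both directions. Of 31 measured, 3 rose, 2 fell and 26 did not pass (5 higher and 7 lower adjusted over the list alone). Pgf, which encodes placental growth factor, rose 3.12-fold (1.64, adjusted p = 1.8e-13), and the platelet-derived growth factor genes Pdgfb (0.75) and Pdgfa (0.65, chosen after its value was seen) rose as well. Angpt1, which encodes angiopoietin 1, fell by 0.76 and the guidance gene Sema3a fell by 0.70. The calls of Pdgfb, Angpt1 and Sema3a ended in 3, 3 and 5 of the 6 fits with an array left out, with adjusted p of up to 0.0804 (without GFP replicate 1), 0.128 (without GFP replicate 3) and 0.225 (without GLI1 replicate 2). The call of Pdgfa ended in all 6 of these fits (adjusted p of up to 0.326, without GFP replicate 3) and without moderation (adjusted p = 0.199). As a list they did not shift (median -0.08, -0.12 to 0.05 with 1 array left out, mean 0.00, tested direction higher, camera adjusted p = 0.836).

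Notch signalling genes were higher as a list with the preset correlation. Of 16, 5 rose, 1 fell and 10 did not pass (6 higher and 2 lower adjusted over the list alone). Lfng, which encodes a glycosyltransferase that modifies Notch receptors, rose 3.32-fold (1.73, adjusted p = 4.9e-15), and Nrarp, a feedback inhibitor and Notch target, rose 2.31-fold (1.21). The target genes Heyl (0.93), Hey1 (0.86) and Hes1 (0.86), chosen after their values were seen, rose too. Hes6, which is expressed in differentiating myoblasts, fell by 0.97, and Notch3 had -0.53 without passing. The calls of Nrarp, Hes6, Hey1 and Hes1 ended without moderation (adjusted p = 0.08, 0.0592, 0.229 and 0.059), and those of Hey1 and Hes1 in 2 and 1 fits with an array left out (adjusted p of up to 0.0643 without GLI1 replicate 1 and 0.0505 without GLI1 replicate 2). The median was 0.13 (camera adjusted p = 0.0021), and the call was lost with an estimated correlation (adjusted p = 0.0962). The Notch median depended on single arrays, at 0.02 without GLI1 replicate 1, 0.07 without GFP replicate 2 and 0.25 without GLI1 replicate 3, and it was 0.05 with array weights. Of 27 BMP and TGF-beta genes 4 rose, 3 fell and 20 did not pass (5 higher and 4 lower adjusted over the list alone), with no shift of the list (median -0.09, -0.22 to 0.03 with 1 array left out, tested direction higher, camera adjusted p = 0.949). Id1, an inhibitor of myogenic factors and a BMP target, rose 2.18-fold (1.13) and Id4 rose 1.97-fold (0.98), whereas Tgfb3 fell by 0.73 and Tgfb2 by 0.65. The calls of Id1 and Id4 ended without moderation (adjusted p = 0.205 and 0.123). The calls of Tgfb3 and Tgfb2 ended in 3 and 5 fits with an array left out (adjusted p of up to 0.168 without GFP replicate 3 and 0.314 without GLI1 replicate 2). Of 31 Wnt pathway genes 2 rose, 0 fell and 29 did not pass (2 higher and 1 lower adjusted over the list alone; median 0.01, -0.07 to 0.11 with 1 array left out, camera adjusted p = 0.567). Wnt4 rose 2.32-fold on the probe set used (1.22), a call that ended without moderation (adjusted p = 0.118), and had 0.34 on another. The call of Wnt10b (0.71) rested on GFP replicate 2: its GFP values had an SD of 1.51, and without that array the difference was -0.16 (adjusted p = 0.843). Sfrp4 (-0.60) and Nkd2 (-0.54) did not pass.

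Interferon and virus response genes were higher by a median of 0.61, the highest median of the 27 lists. Of 29, 13 rose, 0 fell and 16 did not pass (20 and 0 adjusted over the list alone; camera adjusted p = 4.7e-21), and the list's call was lost with an estimated correlation (adjusted p = 0.0516). The chemokine gene Ccl5 rose 2.19-fold (1.13, adjusted p = 3.8e-06) and Usp18, an interferon-induced protease gene, rose 2.12-fold (1.08), a call that ended without moderation (adjusted p = 0.232). The lowest members did not pass, with -0.24 for the interferon gene Ifnb1 and -0.13 for Mx1. Both groups were infected with an adenovirus, and the amount of virus per sample is not given in the sources used here. Of 24 inflammatory cytokine genes 1 rose, 1 fell and 22 did not pass (3 higher and 6 lower adjusted over the list alone; median 0.00, -0.04 to 0.12 with 1 array left out, camera adjusted p = 0.629). Il11 rose as above and Il1b fell by 1.08, a call that ended without moderation (adjusted p = 0.109), while Il33 (0.64) and Saa3 (-0.63) did not pass. Of 21 stress and unfolded protein response genes 2 rose, 0 fell and 19 did not pass (5 and 0 adjusted over the list alone), and the list was higher with the preset correlation (median 0.33, or 0.22 without GLI1 replicate 2; camera adjusted p = 5.1e-05; adjusted p = 0.151 with an estimated correlation). The members that rose were the stress-induced factor Atf3 (0.79) and the heat shock gene Hspa1a (0.69), whose calls ended in 3 and 4 fits with an array left out (adjusted p of up to 0.0795 without GLI1 replicate 2 and 0.327 without GLI1 replicate 3). Herpud1 (-0.19) and Xbp1 (-0.14), genes of the unfolded protein response, did not pass.

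Cell cycle genes did not shift as a list. Of 41, 2 rose, 2 fell and 37 did not pass, with the same counts adjusted over the list alone (median 0.09, 0.03 to 0.10 with 1 array left out, camera adjusted p = 0.619). The replication licensing gene Mcm6 (0.73) and the cyclin gene Ccne2 (0.66) rose, E2f2 fell by 1.04 and the ribonucleotide reductase gene Rrm2 fell by 0.71. The call of E2f2 ended without moderation (adjusted p = 0.117). The calls of Mcm6, Ccne2 and Rrm2 ended in 4, 6 and 5 fits with an array left out (adjusted p of up to 0.147 without GLI1 replicate 3, 0.24 without GFP replicate 1 and 0.235 without GLI1 replicate 2). Of 20 cyclin-dependent kinase inhibitors and p53 targets 1 fell, 0 rose and 19 did not pass, also adjusted over the list alone (median 0.13, 0.06 to 0.26 with 1 array left out, camera adjusted p = 0.481). Gadd45a, a growth arrest gene, fell by 0.93, and Sesn2 (0.54), Cdkn2b (0.47) and Sesn1 (-0.39) did not pass.

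Among metabolic lists, 0 of 29 genes of oxidative phosphorylation and mitochondria passed in limma, over all probe sets or adjusted over the list alone, and 4 higher and 2 lower members had an unadjusted p below 0.05 (median 0.05, -0.02 to 0.17 with 1 array left out, camera adjusted p = 0.232), with Uqcrfs1 at 0.54, Ppargc1b at 0.52, Cox8b at -0.51 and Cox6a2 at -0.40. This list was called without GLI1 replicate 1 (median 0.17, adjusted p = 0.0185). Of 21 glycolysis genes 3 fell, 0 rose and 18 did not pass, also adjusted over the list alone. Eno3, the muscle enolase gene, fell by 0.84 and Pdk4, which encodes an inhibitor of pyruvate dehydrogenase, fell by 0.72, a call that ended in 4 fits with an array left out (adjusted p of up to 0.192, without GLI1 replicate 2); Slc2a4 (0.15) and Aldoc (0.11) did not pass. The glycolysis list was lower (median -0.16, camera adjusted p = 0.0323), but not with an estimated correlation (adjusted p = 0.686), with fry (adjusted p = 0.25), with the most variable probe set of each gene (adjusted p = 0.0581), without GFP replicate 2 (median -0.11, adjusted p = 0.19) or without GLI1 replicate 2 (median -0.06, adjusted p = 0.384). Its median was -0.27 without GLI1 replicate 1. Of 16 sterol synthesis genes 1 fell, 0 rose and 15 did not pass, also adjusted over the list alone. The list was lower (median -0.20, camera adjusted p = 0.0292; adjusted p = 0.153 with an estimated correlation; 0.0848 without GLI1 replicate 2). Dhcr7, the last enzyme of cholesterol synthesis, fell by 0.68, and that call ended in 5 fits with an array left out (adjusted p of up to 0.249, without GLI1 replicate 3). Srebf2 (-0.51), Mvd (0.27) and Idi1 (0.24) did not pass. Of 20 atrophy and autophagy genes 1 rose, 1 fell and 18 did not pass (1 higher and 2 lower adjusted over the list alone; median -0.06, -0.13 to -0.04 with 1 array left out, camera adjusted p = 0.489). Fbxo40, a muscle ubiquitin ligase subunit, fell 2.65-fold (-1.41), a call that ended without moderation (adjusted p = 0.0561), and Foxo1 rose by 0.80, a call that ended in 3 fits with an array left out (adjusted p of up to 0.168, without GFP replicate 1); Foxo4 (0.39) and Trim54 (-0.63) did not pass. Of 22 ribosomal protein genes 0 passed in limma, also adjusted over the list alone or at an unadjusted p below 0.05 (median 0.11, 0.05 to 0.20 with 1 array left out, camera adjusted p = 0.313), with Rpl5 at 0.24, Rpl7 at 0.21, Rpl10a at -0.24 and Rplp0 at -0.08; that list was called without GLI1 replicate 1 (adjusted p = 0.027).

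Markers of other cell types did not all move in a common direction. The medians of the matrix, smooth muscle and fibroblast lists lay below 0, whereas that of the adipocyte list lay above 0. Of 40 extracellular matrix genes 4 fell, 0 rose and 36 did not pass (7 lower and 1 higher adjusted over the list alone; median -0.27, camera adjusted p = 5.1e-05; adjusted p = 0.227 with an estimated correlation). Col12a1 fell by 0.70 and Col6a2 by 0.67, and both calls ended in 5 fits with an array left out (adjusted p of up to 0.261 and 0.319, without GLI1 replicate 2); Col6a3 (0.52) and Timp3 (0.24) did not pass. Of 14 smooth muscle and myofibroblast markers 2 fell, 1 rose and 11 did not pass, also adjusted over the list alone (median -0.23, camera adjusted p = 0.0323; adjusted p = 0.237 with an estimated correlation, 0.0507 with fry, 0.13 without GFP replicate 1 and 0.0848 without GLI1 replicate 2). Synpo2 fell by 0.87, Pdgfrb fell by 0.70 and Smtn rose by 0.83, and the calls ended in 1, 4 and 1 fits with an array left out (adjusted p of up to 0.058 without GLI1 replicate 2, 0.234 without GLI1 replicate 2 and 0.0545 without GFP replicate 3). Of 17 fibroblast and undifferentiated myoblast markers 2 rose, 1 fell and 14 did not pass (2 and 2 adjusted over the list alone; median -0.16, camera adjusted p = 0.567). Id1 rose as above, Id3 rose by 0.73 and the integrin gene Itga7 fell by 0.77, the last 2 calls ending in 5 and 2 fits with an array left out (adjusted p of up to 0.225 without GFP replicate 1 and 0.0908 without GLI1 replicate 2); Tcf4 (-0.59) did not pass.

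Of 18 adipocyte markers 2 rose, 2 fell and 14 did not pass (4 higher and 3 lower adjusted over the list alone). Plin4, which encodes a lipid droplet coat protein, rose 4.63-fold (2.21, adjusted p = 4.4e-25) and Dgat2, an enzyme of triglyceride synthesis, rose 2.21-fold (1.15). The fatty acid transporter gene Cd36 fell by 0.98 and the lipase gene Lpl fell by 0.73, a call that ended in 4 fits with an array left out (adjusted p of up to 0.262, without GLI1 replicate 1). The calls of Dgat2 and Cd36 ended without moderation (adjusted p = 0.0873 and 0.114). The list was higher (median 0.15, camera adjusted p = 0.0292), but not with an estimated correlation (adjusted p = 0.153), without GFP replicate 1 (median 0.07, adjusted p = 0.0669) or without GLI1 replicate 1 (adjusted p = 0.113). Its median was also 0.07 without GLI1 replicate 2. Of 15 chondrocyte markers 2 rose, 0 fell and 13 did not pass, also adjusted over the list alone (median -0.06, -0.08 to 0.11 with 1 array left out, tested direction higher, camera adjusted p = 0.478). Sox9, the chondrogenic transcription factor gene, rose 2.38-fold (1.25, adjusted p = 1.4e-07). The call of Sox6 (0.66) rested on GFP replicate 2, without which the difference was 0.04 (adjusted p = 0.966). Col10a1 (-0.37) and Acan (-0.23) did not pass. Of 12 osteoblast markers 1 rose, 0 fell and 11 did not pass, also adjusted over the list alone (median 0.01, -0.12 to 0.09 with 1 array left out, camera adjusted p = 0.79); Dlx3 rose by 0.69, a call that ended in 4 fits with an array left out (adjusted p of up to 0.19, without GFP replicate 1), and Alpl (0.18), Pth1r (-0.30) and Col11a1 (-0.28) did not pass. Of 14 endothelial markers 0 passed in limma, also adjusted over the list alone, and 2 higher and 0 lower members had an unadjusted p below 0.05 (median 0.14, -0.02 to 0.27 with 1 array left out, camera adjusted p = 0.136), with Flt1 at 0.48, Kdr at 0.47, Tek at -0.23 and Sox17 at -0.22; the list was called without GLI1 replicate 3 (median 0.27, adjusted p = 0.0399). Of 18 neural and floor plate markers 1 rose, 0 fell and 17 did not pass, also adjusted over the list alone (median 0.05, -0.08 to 0.13 with 1 array left out, mean -0.01, camera adjusted p = 0.943). Irx3 rose by 0.73, a call that ended in 4 fits with an array left out (adjusted p of up to 0.121, without GFP replicate 2), and Gfap (0.24), Nes (-0.43) and Olig1 (-0.30) did not pass. In all, 12 of the 27 lists were called by camera, 5 higher and 7 lower. Splits of the arrays that mix the groups gave 3 to 9 lists with the preset correlation. With an estimated correlation 4 were called, namely Hedgehog targets (with Gli1 in the list), myogenic regulators, sarcomere proteins, and excitation-contraction and neuromuscular junction. Fry, which asks a different question, ended the calls of the glycolysis and smooth muscle lists only (fry adjusted p of 0.00456 for the interferon list and 0.00258 for Notch). In the directions in which 0 members of a list with calls passed, limma's unadjusted p was below 0.05 for 4 higher cyclin-dependent kinase inhibitors and p53 targets, 3 lower Wnt genes, 1 higher Hedgehog component, 1 higher myogenic regulator, 1 higher matrix gene, 1 lower neural marker and 0 members of the other such lists.

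**Figure D3:**
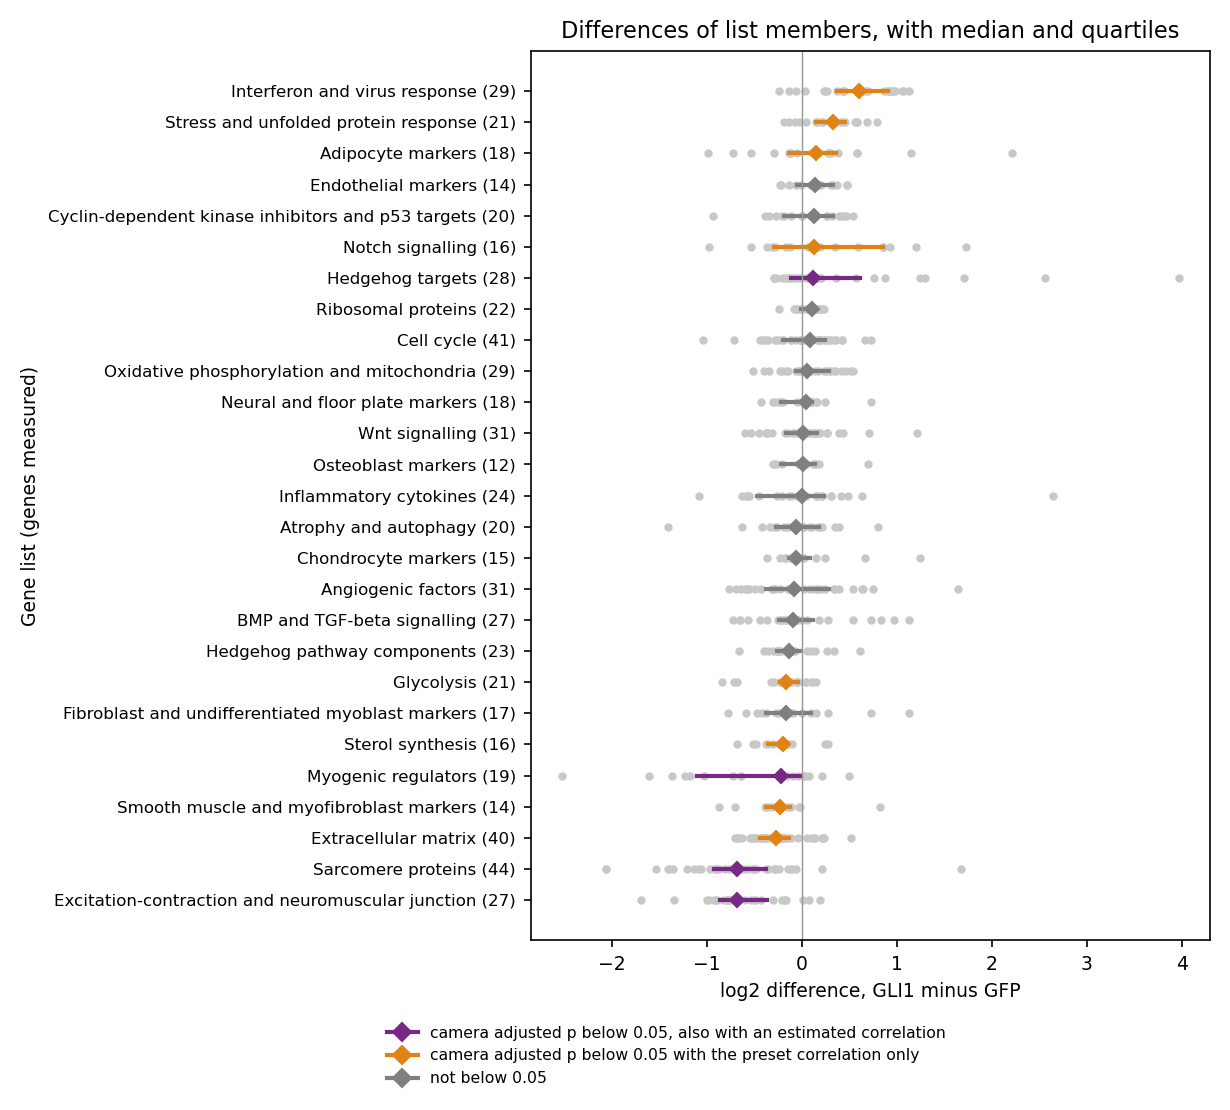
Log2 differences between the GLI1 and GFP groups (horizontal axis) for the measured members of each of the 27 gene lists (grey points), with the list's median (diamond) and quartiles (line). Lists called by camera with both correlations are purple, with the preset one alone orange, and others grey; medians ran from -0.68 for the sarcomere and the excitation-contraction lists to 0.61 for the interferon list.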

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

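The fit without variance moderation, and all alternatives for genes chosen after their values were seen, were added after the data were seen; the other alternatives were planned. Filters on dim probe sets were not run, since centring removed the signal level, and the trended prior therefore followed the centred mean, not signal. The Ptch1 difference (2.29 to 2.68) and the shift of the Hedgehog target list (median 0.06 to 0.17) kept their direction and call under each alternative run. The counts moved by over 1.5 times to 594 lower with array weights, to 232 lower at an adjusted p below 0.01, and to 100 higher and 148 lower without moderation, where each gene is judged by its own spread on 4 residual degrees of freedom. With 1 array left out, which lowers the number of samples, 213 to 291 were higher and 195 to 322 lower. The number of shifted lists was 4 with an estimated correlation, which allows for genes that move together, and 9 to 13 with 1 array left out. Of the 68 named genes past the threshold, 31 kept direction and call under each alternative, 36 lost the call without moderation and 26 in at least 1 fit with an array left out. Of 45 genes chosen after their values were seen, Marchf11 not among them, 26 lost the call without moderation and 9 of them in at least 1 fit with an array left out.

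The residuals showed no clear pairing by replicate number: those of same-numbered arrays correlated at 0.24, -0.11 and -0.03. Not every array correlated best with its own number (GFP replicate 2 with GLI1 replicate 3, 0.31). Residuals cancel within a group, which ties these correlations to each other, so a shared culture or day is not excluded. With the number as a block, 373 probe sets were higher and 397 lower, 12 lists shifted, and Il33 and Trim54 passed; it changed no other call of a named gene or list.

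Signs changed as follows, and the cause was not tested. With array weights Sln was -0.049, Alpl -0.068, and the medians of the inflammatory list -0.028, the osteoblast list -0.051 and the neural list -0.034. With probe sets averaged Foxf1 was 0.065. With 1 array left out, Wnt10b, called with all arrays, ranged from -0.16 to 1.16. Genes short of the threshold ranged from -0.13 to 0.25 (Sln), -0.11 to 0.44 (Alpl), -0.16 to 0.33 (Aldoc), -0.23 to 0.0023 (Xbp1), -0.61 to 0.034 (Olig1), -0.013 to 0.49 (Mvd), -0.27 to 0.094 (Mx1), -0.38 to 0.015 (Tek), -0.18 to 0.012 (Rplp0) and -0.051 to 0.42 (Mylk4). List medians ranged from -0.044 to 0.12 (inflammatory), -0.12 to 0.086 (osteoblast), -0.085 to 0.13 (neural), -0.12 to 0.046 (angiogenic), -0.22 to 0.035 (BMP and TGF-beta), -0.081 to 0.11 (chondrocyte), -0.067 to 0.11 (Wnt), -0.017 to 0.27 (endothelial) and -0.022 to 0.17 (mitochondria).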

Other observations

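The tests of the muscle and interferon patterns, the tests of the 3 added gene lists and the genes outside the fixed lists that are named first were chosen after results they bear on were seen; the tests of neighbouring genes and of other splits were fixed before their values were computed. Of 57 genes of neuropeptides and peptide hormones listed afterwards 6 rose and 0 fell in limma (median 0.04): next to galanin these were Sct (2.33), which encodes secretin, Qrfp (2.04), Penk (1.05), which encodes proenkephalin, Nppb (0.98) and Cck (0.66). Of 50 epidermal genes listed afterwards 9 rose, 1 fell and the list's median was -0.02; the risers included Krt16 (1.81), Slurp1 (1.74), Hr (1.64) and Krtdap (1.23), and Trp63 fell by 1.01. Of 42 activity-induced genes 6 rose and 0 fell in limma (median 0.28); Klf4 (1.41) and Nr4a1 (1.04) rose beside Arc and Rcan1. Other single genes, which stand for no group tested, were Cd24a (2.28), which encodes a surface protein, Nptx1 (2.12), which encodes a neuronal pentraxin, Rdh10 (1.60) and Cyp26b1 (1.18) among the rises. Among the falls, Ank1 fell by 1.46, Prkag3 by 1.43, Car3 by 1.34, Klhl31 by 0.98 and Xirp1 by 1.21. Of a serine protease inhibitor cluster, Serpinb9b rose (1.76) while Serpinb9d (-0.80) and Serpinb9e (-0.80) fell; probes of such paralogs can share signal. With 1 array left out, the calls of Cck, Serpinb9d and Serpinb9e ended in 6, 1 and 1 of the 6 fits (adjusted p of up to 0.28 without GFP replicate 3, 0.0595 without GLI1 replicate 1 and 0.0519 without GLI1 replicate 1). Without moderation the calls of Sct, Qrfp, Penk, Nppb, Cck, Hr, Krtdap, Trp63, Nr4a1, Nptx1, Rdh10, Car3, Xirp1, Serpinb9d and Serpinb9e ended, with adjusted p from 0.0505 to 0.172.

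The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 349 probe sets higher, 366 lower and 12 shifted lists. Of the 10 splits 1, the real one, reached each of these. The highest other split gave 10 probe sets in a single direction. Each of the others mixed the 2 groups, and they gave 3 to 9 lists with the preset correlation. A split with 0 probe sets called gave 9 lists. Such a split keeps part of the real difference, since its sides hold unequal numbers of GLI1 arrays. It therefore cannot show whether a list's call at that setting needs the real grouping.

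The fall of the muscle genes was weighed against 2 explanations, a smaller share of myotubes and a difference between whole arrays. The share of myotubes at lysis is not given in the sources used here, and a smaller share would not exclude an effect of GLI1. A smaller share would raise the markers of the unfused cells, and it cannot be told apart here. C2C12 is a myoblast line, so matrix, fibroblast and smooth muscle genes need not mark those cells. The 70 such genes outside the muscle lists had a median of -0.24 (95% bootstrap interval -0.33 to -0.18). The 17 markers of fibroblasts and undifferentiated myoblasts alone had -0.16 (-0.37 to 0.10), with 2 risers and 1 faller. These intervals resample the genes of a list and not the arrays, so they measure the spread between genes. A difference between whole arrays is argued against by a sarcomere median of -0.67 after quantile normalization, against -0.68 before. The array medians already lay between -0.03 and 0.02, so there was little to move. Scaling that depends on the signal level could not be examined, because centring removed that level. The difference that the design names, expression of GLI1, stays open and was not tested further.

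The rise of interferon genes did not rest on a single GLI1 array, since the list's median was at least 0.57 without any of them. Unequal virus load may account for it: nothing on the arrays measured the virus, and the load is confounded with the group. The inflammatory list's median of 0.0022 (95% bootstrap interval over its genes -0.26 to 0.21) decides nothing because its members went both ways. An effect of GLI1 and one of the virus cannot be told apart here.

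Called genes often lay side by side in the genome, such as Acy3 (3.15) and Aldh3b2 (2.34), Ttn (-2.06) and Ccdc141 (-0.68 on the probe set used), or Grasp (1.30) and Nr4a1 (1.04). On that probe set, the call of Ccdc141 ended in 5 fits with an array left out (adjusted p of up to 0.351, without GFP replicate 3). Averaged over its probe sets, Ccdc141 fell further, at -1.31 (adjusted p = 1.2e-07 in limma). The calls of Ccdc141, on the probe set used, and Grasp ended without moderation (adjusted p = 0.145 and 0.0633). By gene order in assembly GRCm38.p6, 41 neighbouring pairs of the 603 called genes placed moved in the same direction, against a median of 9 and a maximum of 19 in 1000 shuffles of the calls, and 4 moved in opposite directions (median 9). Families of genes named alike are argued against as the whole cause, since 26 pairs without a common symbol stem of 3 letters remained (shuffled 95th percentile 13). Of these, 23 did not overlap in that assembly (12). The share of shuffles with as many was 1.0e-03, the smallest that 1000 can give. The sequences and positions of the probes were not examined, so signal shared between probes is not excluded. Shared regulation of neighbours may account for the excess, as a hypothesis; clusters that any change of muscle state would move were not separated from an effect of GLI1.

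It was asked whether the 3 groups of genes above rose more widely than the members that had drawn attention, by camera over the remaining members of 3 lists. Tables of called genes had been seen when the lists were written, and 1 of the remaining epidermal genes, 5 of the activity-induced and 2 of the peptide hormone genes belonged to the fixed lists. The 37 other activity-induced genes were higher (median 0.17, camera adjusted p = 1.0e-04 over 3 lists, 3.3e-05 before adjustment), with Klf4 as the only one of them that passed, and this was lost with an estimated correlation, which gave 0.0748 before adjustment. Without Klf4 and the 5 genes of fixed lists, the median of the other 31 was 0.17 (camera adjusted p = 0.00329; adjusted p = 0.361 with an estimated correlation), so a wider rise stays a hypothesis. The 40 other epidermal genes had a median of -0.11, and 0 passed in limma (1 higher and 1 lower at an unadjusted p below 0.05; camera adjusted p = 0.699, 0.466 before adjustment). The 51 other peptide hormone genes had a median of -0.0062, and 0 passed in limma (1 higher and 2 lower at an unadjusted p below 0.05; camera adjusted p = 0.741, the value before adjustment too). Leaving out called genes means that these last results exclude nothing about the lists as a whole.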
